A study of Arabidopsis thaliana with 2 samples.

How the data were processed

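Total RNA from root tips of Arabidopsis Col and atphb3 seedlings was copied into cDNA with random primers and sequenced on an Illumina instrument, per the labels' protocols. The series held 1 library per group, and the group of each library was taken from its title. The deposited table listed 26425 transcripts with their length, position and description. Per the file headers, the authors gave for each transcript a read count, an RPKM value per library, the log2 ratio of atphb3 over Col, a p-value and a false discovery rate. The aligner, the counting tool, the genome build and the authors' test were not given in the sources used here. The values showed that the authors' RPKM divided each count by transcript length and by the column's total, that a count of 0 was deposited as an RPKM of 0.01, and that the deposited log2 ratio was that of the RPKM values. The deposited p-value and false discovery rate compare 1 library with 1 library and were not used.

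Transcript counts were summed to 22937 loci. Of these, 3069 had several listed transcripts. Those loci had a median of 17 reads in Col against 81.5 for loci with 1 transcript, and 25.3% against 61.2% were measured. How reads that fit more than 1 transcript of a gene were counted is not given in the sources used here, so levels of such loci are uncertain. The protocols name no strand-marking kit, so reads of overlapping or antisense genes could not be told apart. Of 120 loci chosen by the naming rule, 4 overlap another listed locus. Positions are those of the deposited table, whose build is not named. They were compared with the RefSeq annotation of TAIR10.1, which held 22759 of the loci, and 98.5% of the listed spans lay inside the RefSeq locus. Symbols came from that annotation and from the gene lists.

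Counts were scaled to the library total as CPM. A log2 ratio was taken after adding 0.5 reads to each count. Fold values of single genes are ratios of CPM without this addition, with the 95% Clopper-Pearson interval conditional on the summed reads. A gene at 0 reads in 1 library was compared with a floor of 3 counts per library, or 0.403 CPM in Col and 0.406 in the library labelled atphb3. Reads carried no molecular identifiers, so intervals and floors cover counting error only. With these depths 1 read equalled 0.134 and 0.135 CPM. A locus was measured with 50 or more reads in at least 1 library.

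The 28 gene lists with 603 members, and the 2 organelle genomes, were fixed before the data were examined, as were the tests and the naming rule. A member whose locus carries only other names in the annotation was left out, which removed 7. Of the rest, 538 matched by symbol, 31 had no symbol in the annotation and 27 had been listed by locus alone. For each list the median log2 ratio of measured members was given with a 95% bootstrap interval over members (2000 draws) and its percentile among 10000 random lists of equal size, matched on mean expression in 10 bins. This percentile describes these libraries. Genes were named by 3 rules: the prohibitins; the 12 highest and 12 lowest measured genes by the bound of the counting interval nearest 0; and in each list up to 4 members at least 2-fold apart with the largest difference, or else its 2 most expressed members. Not each of these genes is named in the text. Lists of clock genes and of further leaf genes were drawn up after the main values had been seen.

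Alternatives fixed in advance were TMM scaling (edgeR 4.0.16), median of ratios scaling (DESeq2 1.42.0), a total over nuclear genes, the authors' RPKM, a pseudocount of 2 reads, no filter, a minimum of 200 reads, limits of 4-fold and 1.5-fold, intervals wholly beyond 2-fold, and means in place of medians. Chosen after seeing the data were counts by transcript, loci with 1 transcript only, totals without the 10 most abundant loci, and the removed members put back. TMM factors were 0.978 for Col and 1.02 for the library labelled atphb3. The calculations were tested on simulated Poisson counts for atphb3 over Col, with 200 loci changed 4-fold. There, all 199 changed loci that were measured passed 2-fold in the right direction. In all 12509 loci were measured, of which 2 unchanged ones lay at least 2-fold apart in either direction. Of the intervals, 95.1% held the true ratio. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 were used.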

Results

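RNA from the root tip of Arabidopsis thaliana was sequenced in the wild-type accession Col and in atphb3, a mutant named for PROHIBITIN 3 (PHB3), a scaffold protein of the inner mitochondrial membrane. Each group held 1 library, so there were no replicates. Seeds were kept cold for 3 days, and seedlings were grown at 20 °C with 16 h of light and 8 h of dark. The labels gave the root tip as the sampled site, while a second sentence of the extraction protocol also named shoots. The deposited table assigned 7451022 reads to transcripts in Col and 7384348 in the library labelled atphb3. Summed over transcripts, 22937 loci had reads, and 12931 of them had at least 50 reads in at least 1 library and are called measured here. Intervals on ratios of single genes are 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only and compare these libraries, not the genotypes.

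PHB3 mRNA was not lower in the library that carries its name. PHB3 (AT5G40770, chromosome 5, 16314850 to 16316719, minus strand) had 915 reads in Col and 863 in the library labelled atphb3, a ratio of 0.952 (0.866 to 1.05). Its level therefore gave no check of the label, and the wording "the library labelled atphb3" is kept throughout, since every direction drawn here rests on that label. Other prohibitin genes were higher there. PHB1 (AT4G28510, chromosome 4, 14084749 to 14086844, minus strand) was 3.07-fold higher (2.76 to 3.42), and PHB4 was 4.42-fold higher (2.99 to 6.70) on 32 and 140 reads. PHB6, with 7 and 21 reads, and PHB2, with 7 and 10, were too shallow to be measured. The 3 measured prohibitins had a median log2 ratio of 1.62, with an interval of -0.07 to 2.13 that included 0, and of 0.77 over those with at least 200 reads or with 1 listed transcript. PHB4 and PHB2 have several listed transcripts, a class of loci that drew few reads in this table.

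The main comparison asked how the root tip transcriptome of the mutant differs from that of Col under normal growth. Genes that plants switch on when mitochondria are impaired were far higher in the library labelled atphb3, as were group X ethylene response factors. Nuclear photosynthesis genes and evening-phased clock genes were far lower. Of 14 measured iron deficiency genes, 6 were at least 2-fold higher and 8 lay within 2-fold. Of 14 measured cytokinin genes, 6 were at least 2-fold lower, 1 was higher and 7 lay within 2-fold. In all, 1259 measured loci were at least 2-fold higher and 1301 at least 2-fold lower, that is 9.74% and 10.1% of those measured, and 80.2% lay within 2-fold. At least 8-fold differences were seen in 113 loci in the higher and 155 in the lower direction. These are counts by size, with no test across genotypes. The labels give no time of harvest.

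**Figure D1:**
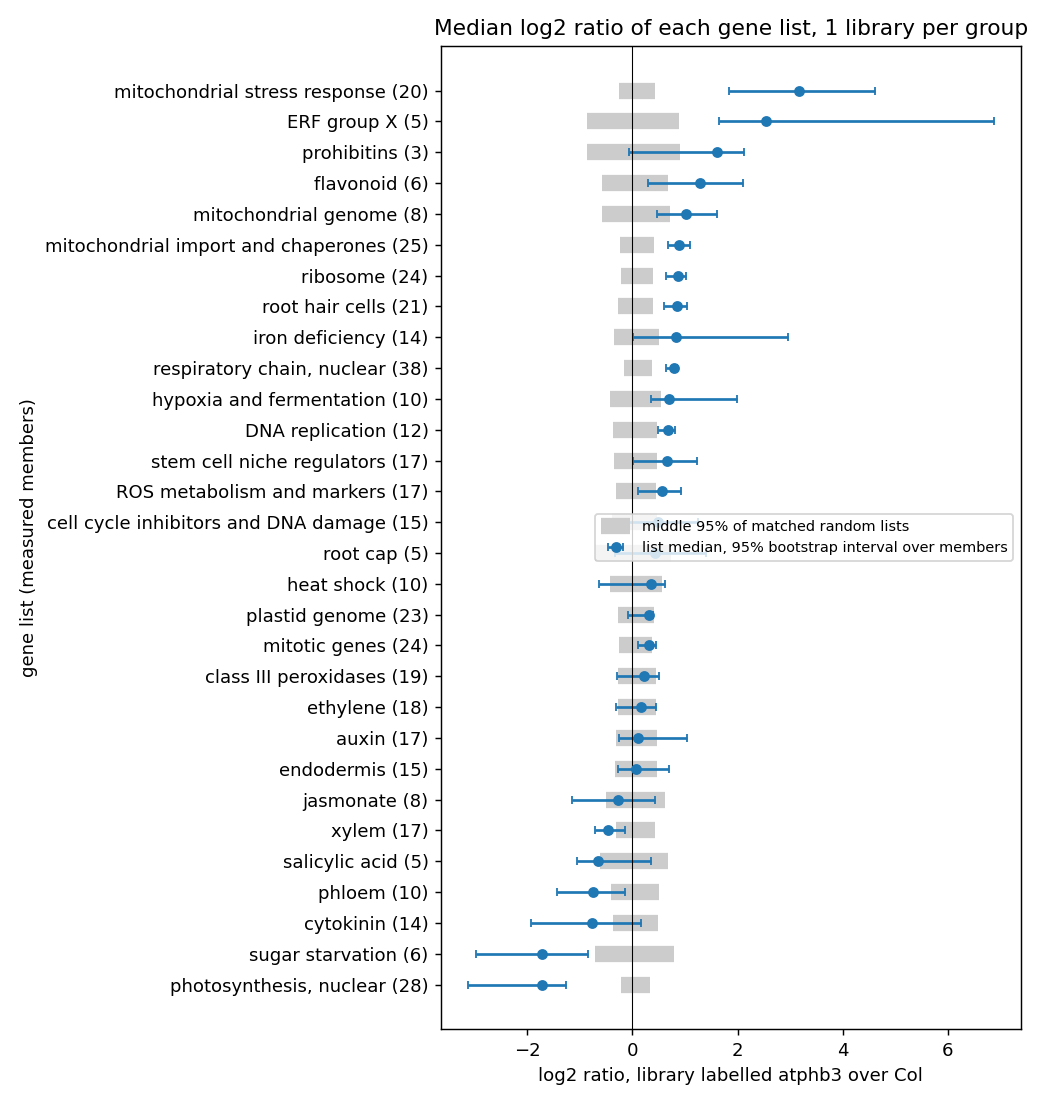
Median log2 ratio of the measured members of each of 30 gene lists, the library labelled atphb3 over Col (x axis), with the number of measured members in brackets (y axis). Points are medians, whiskers their 95% bootstrap intervals over members, and grey bars the middle 95% of 10000 random lists matched on expression; the mitochondrial stress response list lies farthest right at 3.18 and the photosynthesis list farthest left at -1.72.

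The mitochondrial stress response was the list with the largest median difference of the 30 examined. Of its 20 measured members, 17 were at least 2-fold higher in the library labelled atphb3, 3 lay within 2-fold and 0 were 2-fold lower. The median log2 ratio was 3.18 (95% bootstrap interval over members 1.84 to 4.61), above each of 10000 random lists matched on expression. AT12CYS-2 (AT5G09570, chromosome 5), which encodes a small twin-cysteine mitochondrial protein, went from 4 to 2204 reads, a 556-fold difference (217 to 2042). NDA1 and NDB4, alternative NAD(P)H dehydrogenases that bypass complex I, were 90.5-fold (43.7 to 226) and 51.2-fold (36.3 to 74.7) higher. AT2G41730, a gene of unknown function, was 62.5-fold higher (42.8 to 95.1). AT12CYS-2, NDA1, NDB4 and AT2G41730 had 4, 7, 33 and 27 reads in Col. They were measured through the library labelled atphb3 alone, so the difference itself helped decide that they entered. With no filter on reads the list's median was 2.81, and over genes with at least 200 reads it was 3.71.

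**Figure D2:**
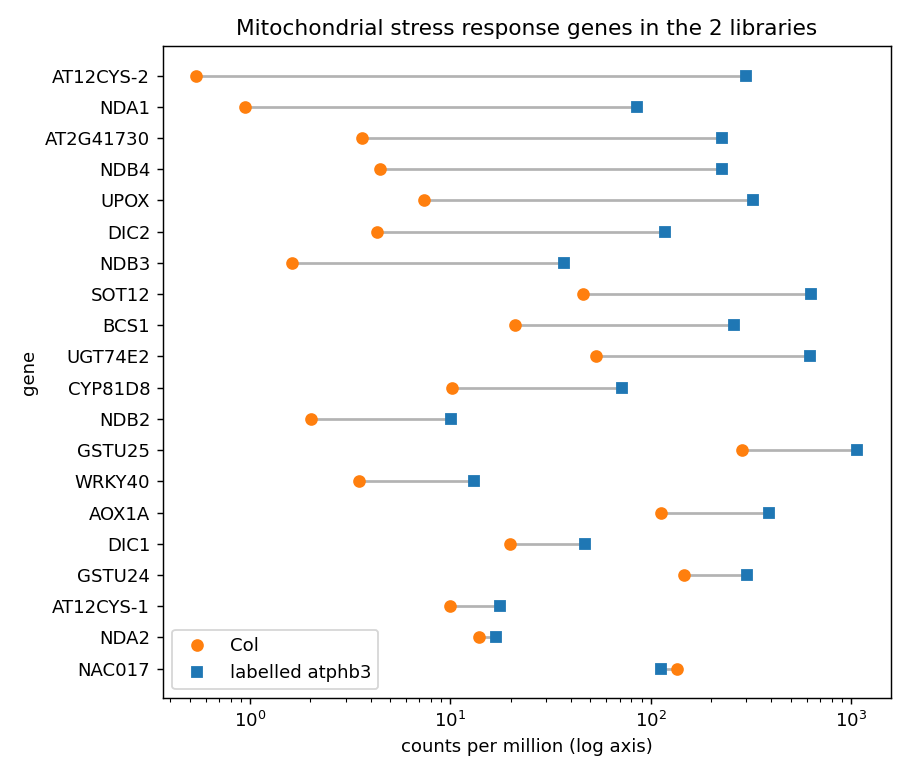
CPM, reads scaled to the library total (log x axis) of the 20 measured mitochondrial stress response genes (y axis) in Col (circles) and the library labelled atphb3 (squares), 1 library each, joined by a line per gene. AT12CYS-2 lies farthest apart, at 0.537 against 298 CPM, and 19 of the 20 genes had a log2 ratio above 0.

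Genes for the mitochondrial machinery itself were also higher, by smaller factors. Among 25 measured import components, chaperones and proteases, 8 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.89 (0.68 to 1.09). The chaperone MTHSC70-1 was 3.54-fold higher (3.39 to 3.71) and the import protein TIM10 was 5.20-fold higher (3.40 to 8.25). TIM10 overlaps another listed gene, so its reads are uncertain. Of 38 nuclear genes of the respiratory chain, 10 were at least 2-fold higher and 0 lower, with a median of 0.79 (0.65 to 0.85). CYTC-2, a cytochrome c gene, was 3.20-fold higher (2.76 to 3.71). Both medians lay above each random list. The mitochondrial genome itself had 8 measured genes, of which 4 were at least 2-fold higher, with a median of 1.02 (0.47 to 1.60), at the 99.8th percentile. The median was 0.43 over genes with at least 200 reads. Of the 4, ATMG00690, ATMG00660 and ATMG00030 are described as hypothetical proteins, and ATMG00090 overlaps another listed locus. The reads of all 65 listed mitochondrial loci together were 1.37-fold higher, at 23217 in Col and 31574 in the library labelled atphb3. Most of them came from ATMG00020, described as a 26S ribosomal RNA, with 14917 and 19967 reads. Ribosomal and nucleolar protein genes were higher as well. All 24 measured members had a log2 ratio above 0, 9 of them at least 2-fold, with a median of 0.86 (0.65 to 1.03), and FIB2, a nucleolar fibrillarin, was 2.44-fold higher (2.22 to 2.68). Markers of root tissues differed by similar sizes, with medians of 0.85 for root hair, -0.46 for xylem and -0.76 for phloem genes.

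Group X of the ethylene response factor family, a set of transcription factors linked to wounding, regeneration and stem cell division, was higher throughout. Its 5 measured members were each at least 2-fold higher in the library labelled atphb3, with a median log2 ratio of 2.55 (1.64 to 6.88), above each random list. With the member at 0 reads set to its bound the median was 2.56, and the mean was 3.71. ERF115 went from 1 to 57 reads, a 57.5-fold difference with a wide interval (9.92 to 2311). ERF114 had 0 reads in Col and 58 in the other library, 19.5-fold higher when Col is set to a floor of 3 counts per library. Its counting interval began at a log2 ratio of 3.94. Both ERF115 and ERF114 were measured through the library labelled atphb3 alone. With no filter on reads the median of the list was 2.37. RAP2.6 was 5.89-fold (4.64 to 7.56) and RAP2.6L 4.58-fold (3.82 to 5.52) higher. This list was drawn up knowing that ERF115 and ERF114 had been studied in this mutant, so its direction is not independent evidence. Ethylene genes as a whole did not move one way. Of 18 measured, 3 were at least 2-fold higher and 1 lower, and the median of 0.16 (-0.32 to 0.44) lay at the 61.9th percentile. ERF105 was 12.3-fold (8.98 to 17.2) and ERF5 5.39-fold (4.50 to 6.51) higher.

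Several regulators of the root stem cell niche were higher. Of 17 measured, 6 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.65 (0.01 to 1.24), at the 99.8th percentile. The root hair, xylem and phloem markers differed beside them, and the tissue make-up of the sampled tips was not measured. WOX5, which marks the quiescent centre, was 3.45-fold higher (2.17 to 5.68) on 24 and 82 reads. PLT1 and PLT3, PLETHORA factors that maintain the meristem, were 2.64-fold (2.03 to 3.46) and 3.40-fold (2.19 to 5.44) higher, and MP, an auxin response factor, was 2.71-fold higher (2.42 to 3.03). DNA replication genes had a median of 0.68 (0.48 to 0.81) over 12 measured members, above the range that held 95% of random lists, although only 1 was at least 2-fold higher and 1 lower. TSO2, a ribonucleotide reductase subunit, was 3.84-fold higher (3.47 to 4.25), and the cyclin CYCD3;1 was 2.75-fold lower (2.37 to 3.21). Mitotic genes, with a median of 0.32 (0.10 to 0.46) over 24 members, lay at the 94th percentile. Of those, CYCB1;1, a cyclin that is also induced by DNA damage, went from 70 to 192 reads, a log2 ratio of 1.46 (1.07 to 1.89).

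Several DNA damage genes were higher. Of 15 measured cell cycle inhibitors and DNA damage genes, 5 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.49 whose interval of -0.31 to 1.24 included 0. NAC044, which acts in the DNA damage response, was 18.7-fold higher (11.7 to 32.0). PARP1 and BRCA1, both of DNA repair, were 3.79-fold (3.02 to 4.81) and 3.15-fold (2.47 to 4.05) higher. Of 17 genes of reactive oxygen species metabolism and signalling, 4 were at least 2-fold higher and 0 lower, with a median of 0.56 (0.11 to 0.93). Those 4 were the zinc finger factors ZAT10, 14.6-fold higher (11.5 to 18.8), ZAT12, 6.42-fold (5.22 to 7.96), and ZAT11, 3.94-fold (2.62 to 6.09), and the kinase OXI1, 5.51-fold (4.77 to 6.38). Class III peroxidases went both ways, with 2 of 19 at least 2-fold higher, 3 lower and a median of 0.23 (-0.30 to 0.51). With the members that the symbol rule had removed put back, after seeing the data, 4 of 21 were higher, 3 lower and the median was 0.28. PRX34 was 3.74-fold lower (3.57 to 3.91) and PRX44 was 2.34-fold higher (2.11 to 2.59).

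Nuclear photosynthesis genes were lower in the library labelled atphb3, and so were clock genes of the evening. Of 28 measured photosynthesis genes, 22 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.72 (-3.14 to -1.26), below each random list, and a mean of -2.47. The light-harvesting gene LHB1B1 went from 455 to 2 reads, 225-fold lower (62.1 to 1867), and CAB3 from 432 to 4, 107-fold lower (41.5 to 395). The size was uneven, since LHB1B2, named after its value was seen, had 2137 and 2410 reads. Light-harvesting genes have near-identical copies, so the split of reads among them is uncertain. The plastid genome's 23 measured genes did not follow, with a median of 0.32 (-0.09 to 0.39) and 0 genes 2-fold apart. Among the 12 genes lowest in the library labelled atphb3 were FKF1, a blue light receptor of the photoperiod pathway, at 218-fold lower (59.9 to 1802), and ELF4, an evening clock component, at 46.5-fold lower (32.6 to 68.8). Clock genes were then grouped by their known phase, after these values had been seen. All 7 measured afternoon and evening genes were at least 2-fold lower, with a median of -2.80 (-5.52 to -1.65). The 7 include FKF1 and ELF4, whose values had prompted the grouping. FKF1, ELF4, PRR5 and BOA were measured through Col alone. TOC1, ELF3 and GI, measured in both libraries, had log2 ratios of -2.80, -1.66 and -1.005. Of 7 measured morning genes, 5 were at least 2-fold higher and 0 lower, with a median of 1.43 (0.76 to 3.40). Those 5, CCA1, RVE8, LNK1, LNK2 and CDF1, had 4 to 48 reads in Col. They were measured through the library labelled atphb3 alone, so the difference itself helped decide which members entered. All but CDF1 have several listed transcripts, so their levels are uncertain. RVE1 and RVE2, measured in both libraries, had log2 ratios of 0.76 and -0.69.

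**Figure D3:**
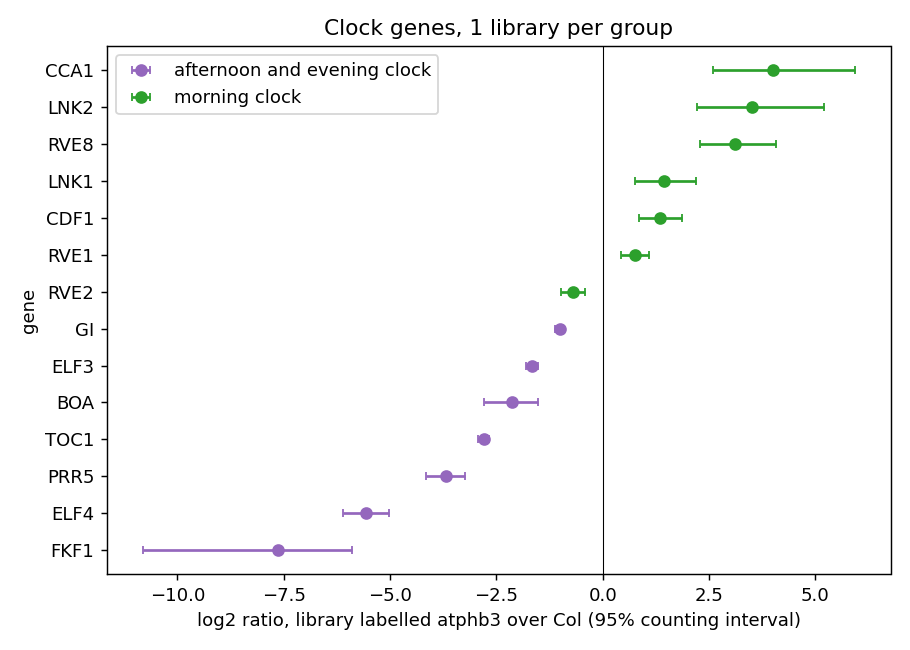
Log2 ratio of the measured clock genes, the library labelled atphb3 over Col (x axis), with 95% counting intervals, for 7 morning genes and 7 afternoon and evening genes (y axis), 1 library per group. CCA1 lies farthest right, with 4 and 64 reads, and FKF1 farthest left, with 439 and 2 reads.

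Several cytokinin response genes were lower. Of 14 measured, 6 were at least 2-fold lower, 1 was higher and 7 lay within 2-fold, and the median log2 ratio was -0.77, with an interval of -1.93 to 0.17 that included 0, at the 0.05th percentile. It was -1.54 over genes with at least 200 reads. Vascular markers were lower beside them, at -0.76 for phloem and -0.46 for xylem genes. The response regulators ARR7 and ARR5 are induced by cytokinin. ARR7 was 19.9-fold lower (13.4 to 31.1), ARR5 had 832 and 165 reads, a log2 ratio of -2.32 (-2.57 to -2.08), and SHY2, an auxin repressor that cytokinin activates in the root, was 7.78-fold lower (6.20 to 9.87). IPT7, a cytokinin synthesis gene, went from 19 to 102 reads, a log2 ratio of 2.41 (1.72 to 3.23). Auxin genes showed no common direction, with 5 of 17 at least 2-fold higher, 1 lower and a median of 0.11 (-0.25 to 1.05), which turned to -0.10 over genes with at least 200 reads. The auxin synthesis gene YUC8 was 3.85-fold higher (2.66 to 5.68) and the auxin carrier PIN2 2.12-fold higher (1.95 to 2.30). Few salicylic acid and jasmonate genes were deep enough to measure. Of 5 salicylic acid genes 1 was at least 2-fold lower, with a median of -0.65 (-1.05 to 0.35), and of 8 jasmonate genes 2 were, with a median of -0.27 (-1.14 to 0.43) and a mean of -1.004, but a median of 0.14 over genes with at least 200 reads. VSP1, a vegetative storage protein induced by jasmonate, went from 148 reads to 1, 147-fold lower (25.9 to 5832).

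Markers of different root cell types moved apart. Root hair genes were higher, with 7 of 21 at least 2-fold higher, 0 lower and a median log2 ratio of 0.85 (0.61 to 1.04), above each random list. LRX2, a cell wall protein of hairs, was 3.19-fold higher (2.76 to 3.70). Phloem genes were lower, with 3 of 10 at least 2-fold lower, 0 higher and a median of -0.76 (-1.44 to -0.13), at the 0.12th percentile, or -0.29 with no filter on reads. SUC2, the sucrose carrier of companion cells, was 15.0-fold lower (11.9 to 19.3), and SEOR1, a sieve element filament protein, 2.71-fold lower (2.37 to 3.10). Xylem genes had a median of -0.46 (-0.71 to -0.13) over 17 members, at the 0.42nd percentile, and XCP2, a xylem protease, was 2.02-fold lower (1.87 to 2.19). Endodermal genes had a median of 0.06 (-0.27 to 0.71) over 15 members, which turned to -0.16 over genes with at least 200 reads and to -0.01 under TMM scaling or without the 10 most abundant loci in the totals. Yet the suberin regulator MYB41 was 12.1-fold higher (8.07 to 19.1) and FAR1, a fatty acyl reductase, 3.57-fold lower (3.08 to 4.17). Root cap genes, with 5 measured, had a median of 0.42 (-0.32 to 1.41), or 0.08 with no filter or over genes with at least 200 reads. The cap regulator BRN2 was 2.67-fold higher (1.84 to 3.95).

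Some iron deficiency genes were much higher in the library labelled atphb3. Of 14 measured, 6 were at least 2-fold higher, 8 lay within 2-fold and 0 were 2-fold lower, with a mean log2 ratio of 1.68 and a median of 0.82 (0.01 to 2.96), above the range that held 95% of random lists. CYP82C4, a cytochrome P450 of the iron response, was 116-fold higher (52.8 to 316), and NAS2, a nicotianamine synthase, 13.7-fold (10.4 to 18.3). FRO2, the root ferric reductase, went from 75 to 1011 reads, a log2 ratio of 3.76 (3.43 to 4.12). Of 10 hypoxia and fermentation genes, 4 were at least 2-fold higher and 1 lower, with a median of 0.70 (0.36 to 1.99), which was 1.78 over genes with at least 200 reads. HRE2, a hypoxia-responsive ethylene response factor, was 61.3-fold higher (26.0 to 190.3), and HB1, a haemoglobin, 7.24-fold higher (5.60 to 9.50). The pyruvate decarboxylases split, PDC1 being 3.97-fold higher (3.45 to 4.59) and PDC2 7.28-fold lower (6.37 to 8.36). Flavonoid genes had a median of 1.28, with an interval above 0 that began at 0.29, and 4 of 6 were at least 2-fold higher, among them TT7, a flavonoid hydroxylase, at 5.11-fold (3.87 to 6.86). Genes induced by sugar starvation were lower, with 5 of 6 at least 2-fold lower and a median of -1.71 (-2.98 to -0.84). DIN10 was 19.8-fold lower (6.47 to 98.8) and TPS10, of the trehalose phosphate synthase family, 3.62-fold lower (3.43 to 3.83). Heat shock genes had a median of 0.36 (-0.63 to 0.62) over 10 members, with 2 at least 2-fold lower. DREB2A, a drought and heat response factor, was 3.23-fold lower (2.37 to 4.47).

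The 12 highest genes, ranked by the lower end of the counting interval, included 5 of the DUF295 family, whose function is unknown. AT5G52940 had 2 and 1090 reads, 550-fold higher (152 to 4547). AT4G25930 had 0 and 560 reads, 188-fold higher when Col is set to the floor of 3 counts. Its counting interval began at a log2 ratio of 7.25. AT5G52930, AT5G54560 and AT5G54450 also belonged to this family. The 12 also held AT2G04050 and AT2G04070, which encode MATE transporters. The first was 105-fold higher (67.7 to 172). The other, with 0 and 394 reads, was 133-fold higher with Col at that floor, and its counting interval began at a log2 ratio of 6.745. DOGT1, a glycosyltransferase of brassinosteroids and toxins, was 125-fold higher (63.0 to 289). Neighbouring DUF295 and MATE genes are similar in sequence, so reads may have been split among them. Among the 12 lowest genes, MLP328, a major latex protein, went from 60911 to 991 reads, 60.9-fold lower (57.2 to 64.9). MRN1, an enzyme of marneral synthesis, was 68.4-fold lower (42.0 to 120.2), the indole glucosinolate methyltransferase IGMT1 40.6-fold (34.6 to 47.9), and the beta-glucosidase BGLU7 66.4-fold (36.9 to 134). TPS12, a terpene synthase, was 57.8-fold lower (32.1 to 116) and overlaps another listed gene.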

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

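The PHB3 ratio stayed within its counting interval under all 6 alternatives tried. Of the list medians, 304 of 305 alternative values stayed within the main bootstrap interval and 0 changed sign where that interval excluded 0. The exception was the mitochondrial genome, whose median log2 ratio was 0.43 over genes with at least 200 reads; fewer genes entered it. Wide intervals hid other moves. With at least 200 reads the medians were 1.78 for hypoxia, -1.54 for cytokinin, 0.77 for prohibitins, 0.14 for jasmonate, -0.10 for auxin, -0.16 for endodermis and 0.08 for root cap, so the sign of jasmonate, auxin and endodermis turned. TMM and the total without the 10 most abundant loci turned the endodermis to -0.01. Means in place of medians gave 3.71 for ERF group X, -2.47 for photosynthesis, 0.03 for heat shock, 1.68 for iron deficiency, -1.004 for jasmonate and -0.02 for class III peroxidases, and no filter gave -0.29 for phloem. Of 714 alternative values for 119 named genes, 706 stayed within the counting interval and 0 reversed. Most of those genes were named for being at least 2-fold apart, while TMM scaling moved log2 ratios by only -0.065. Such genes could hardly reverse, so this count says little. Counts of genes at least 2-fold apart followed the limits used. Without a filter they were 3656 higher and 3580 lower, and with a minimum of 200 reads 671 and 743. At 4-fold they were 300 and 387, at 1.5-fold 2839 and 2372, and with intervals wholly beyond 2-fold 691 and 825. Scaling moved them less: TMM gave 1095 higher and 1421 lower, and leaving the 10 most abundant loci out of the totals, chosen after seeing the data, gave 1081 and 1429. Depth limits the shallow genes, among them ERF115, ERF114 and loci with several transcripts. With 1 library per group no alternative tests how the genotypes vary.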

Other observations

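Other gene families were scanned by their deposited descriptions, after the main values had been seen, over 166 families with 8 or more measured members. Proline-rich extensin-like genes, which encode structural cell wall proteins, were higher in the library labelled atphb3. Of 10 measured, 9 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.33 (1.29 to 2.49). EXT10 was 8.72-fold higher, and the family's reads went from 47167 to 169219. These genes are repetitive and alike, so the level of single members is uncertain. Root hair genes were higher beside them, by less, with a median of 0.85 (0.61 to 1.04). The DUF295 family drew attention through 5 of the 12 highest genes, and 6 of its 8 measured genes were at least 2-fold higher. Those 6 had at most 2 reads in Col and were measured through the library labelled atphb3 alone, so the difference itself decided which members entered. The 15 listed members that were not measured had 109 reads in Col and 168 in the library labelled atphb3. The 2 other measured genes, AT1G27540 and AT1G64840, were 1.07-fold and 1.32-fold higher. Disease resistance genes of the TIR-NBS-LRR class were lower, with 15 of 37 at least 2-fold lower, 1 higher and a median of -0.75 (-1.11 to -0.45). Several of the lower genes were measured through Col alone, among them RPP4 with 88 and 7 reads and AT2G17060 with 71 and 11. Others, such as AT4G23510 with 496 and 205 and RPS4 with 490 and 207, were measured in both libraries. The higher gene, AT5G45220 with 44 and 128 reads, was measured through the library labelled atphb3 alone.

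Several of the most abundant transcripts also differed. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, went from 275488 to 60980 reads, 4.48-fold lower. AT4G23670, a relative of the major latex proteins, was 25.9-fold lower, DR4, a protease inhibitor-like gene, 12.5-fold lower and AT4G11320, a papain-type protease, 15.9-fold lower. MLP329, MLP43 and MLP165 were lower along with MLP328, with 1897, 350 and 435 reads against 11803, 3081 and 1271 in Col. Of these abundant genes, which were picked after their values were seen, the glyceraldehyde-3-phosphate dehydrogenase gene GAPC1 was 3.79-fold, the aldolase FBA8 4.12-fold and the enolase LOS2 2.80-fold higher. The 10 most abundant loci of each library held 9.93% of reads in Col and 6.23% in the library labelled atphb3.

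The tests below were chosen after the patterns they bear on had been seen, and for the leaf markers the bound was set before their own values were seen. The mitochondrial stress response genes were higher in the library labelled atphb3. A few abundant genes taking the reads of 1 library are argued against, since they would shift all genes alike, and the median log2 ratio of all measured genes was 0.076 (0.062 to 0.091) against 3.18 (1.84 to 4.61) for the list. Loss of reads between transcripts is argued against as well, because the 18 members with 1 listed transcript had a median of 3.59 (1.84 to 5.10). A difference in culture or harvest other than genotype cannot be told apart from the genotype, with 1 library per group. An effect of the mutation is a hypothesis that stays open beside it.

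Light-harvesting and evening clock genes were lower in the library labelled atphb3. Harvest at different times of day is a candidate explanation. FKF1, ELF4 and LHY had prompted the test and were left out. The morning genes' median then lay 3.54 (2.35 to 6.65) above that of the afternoon and evening genes on the log2 scale. The read filter can widen this gap. The 5 morning genes at least 2-fold higher were measured through the library labelled atphb3 alone, PRR5 and BOA through Col alone. Less green tissue stays open for the photosynthesis genes. Only 3 of 10 other leaf markers were measured, at a median of -2.86 (-4.26 to -1.68), GDCH and CA1 through their Col reads alone. All 7 listed gave -1.68 (-2.86 to 0.71). Among the shallow ones, HPR was at -1.90 (-3.57 to -0.66). GLDT, AGT and GLDP1 were at 0.20, 0.81 and 0.71, with counting intervals that included 0. The plastid genome did not go lower, as its 23 measured genes had a median of 0.32 with 0 genes 2-fold lower. It cannot decide about green tissue, since roots hold plastids too. Plastid loci also held only 0.22% of reads in Col and 0.26% in the library labelled atphb3. LHB1B2, with 2137 and 2410 reads, decides nothing, as a single gene picked after its value was seen. Its reads may be split with near-identical copies, and 27 of 28 measured photosynthesis genes had a log2 ratio below 0. For the clock, less tissue would lower the morning genes, whose median was 1.43 (0.76 to 3.40). That median cannot decide it, since the 5 genes at least 2-fold higher were measured through the library labelled atphb3 alone. RVE1 and RVE2, measured in both libraries, went opposite ways, at 0.76 and -0.69. A clock altered by the mutation stays open and untested, and how many of the other differences follow the time of day was not tested.

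PHB3 mRNA was at a similar level in both libraries. Swapped labels are argued against by the mitochondrial stress response list, whose median log2 ratio of 3.18 (1.84 to 4.61) would be below 0 if the labels were exchanged and the mutant were the stressed plant. That argument takes for granted that loss of PHB3 impairs mitochondria. A lesion that leaves the mRNA level in place stays open, since the table gives no reads by position and the labels do not describe the allele. Whether the library came from another line was not tested.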
